A study of Mus musculus with 8 samples.

How the data were processed

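Whole blood of mice was profiled on 8 Affymetrix arrays with 1 dye channel. Per the labels, 4 arrays carried blood of control animals kept at room condition and 4 carried blood of animals kept in a sealed hypoxic chamber. There the oxygen content of the gas was lowered from 21% to 8% over 14 days, and blood was drawn from the vena cava after 15 days. Per the labels' protocols, total RNA came from 100 µl of blood in the control group and from 500 µl in the hypoxia group, so that blood volume and group coincide. The RNA was copied with a T7-oligo(dT) primer, amplified in 1 cycle and labelled with biotin. The numbers 1 to 4 in the labels name the samples of each group. The labels do not state in so many words that each number is a separate animal, so p-values measure the spread between these samples.

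The deposited value table gives one linear intensity for each of 45101 probe sets on each array. The submitters' processing notes name GCRMA, RMA and Partek without a role or a version, and the step that made these intensities is not given in the sources used here. On every array the mean without the lowest and highest 2% of probe sets was 500, which is the trace of a global scaling. No log scale and no common distribution across arrays was present, and the median intensity ranged from 163 to 245. The assignment of columns to samples was known from the table itself, so the direction of each difference is settled.

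A second deposited table holds the authors' own comparison of hypoxia with control by SAM (significance analysis of microarrays) for 19949 probe sets, of which 33 were control probe sets. Per the file headers it gives a SAM score, a signed fold change, a fold ratio, the difference of group means and a q-value in percent. The difference is on the log2 scale, since raising 2 to that power gives about the deposited fold ratio. These differences are not those of the deposited intensities (Pearson r of 0.870 across probe sets), so they were made from other values, and the rule that chose the listed probe sets is not given in the sources used here. The authors' table was described and was not tested again.

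For the comparison of groups, intensities below 1 were set to 1 (14 values) and log2 was taken. The array's 64 control probe sets were set aside, and the other 45037 were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior, no covariate). P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a change. All adjusted p-values of single probe sets named by their ID come from this limma fit. Differences are hypoxia minus control. The step was tested on simulated data with 45037 probe sets, 50 of them changed at each of 4 sizes. There 0% of changes of 1 log2 unit were recovered, 36% of those of 2, 68% of those of 3 and 94% of those of 4, with 7 false calls. The simulation gave both groups the spread of the control arrays and placed the changes in probe sets brighter than the median. On the real arrays the median SD in the brightest 10% of probe sets was 1.37 times as large in hypoxia as in control. Dim probe sets varied more, with a median control SD of 1.63 log2 units in the dimmest 10%. These points would lower recovery on the real arrays. The simulation also held only 200 changed probe sets, whereas 2816 were called on the real arrays, which makes the adjusted threshold less strict there. The recovery rates are thus rough guides and no bound in either direction, and those for the real data were not measured. With 4 arrays per group, the number of arrays limits the precision, and small changes were mostly out of reach of this test.

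The plan written before the data were examined called for 1 probe set per gene, 30 gene lists (12 blood cell, tissue and platelet marker lists, a list of reference genes and 17 pathway lists), differences between leukocyte classes and a rule for the genes to name. The files do not pair probe set IDs with genes, and the gene table used here for names (assembly GRCm38.p6) holds no probe set IDs, so 0 of the 45037 probe sets tested received a gene name. All probe sets were therefore tested on their own. Of the 30 lists, 3 had any member that could be named: reference genes (Actb and Gapdh), iron handling (Tfrc) and hypoxia-induced glycolysis (Gapdh). None reached the minimum of 5 members set beforehand, and neither the lists nor the leukocyte classes were tested. The rule for named genes took the 12 largest rises and the 12 largest falls among calls whose 4 hypoxia values all lay on one side of the 4 control values, the leading members of each list, and 21 genes fixed by name. Without gene names, the 2 largest rises and the 2 largest falls are given by probe set ID, and of the genes fixed by name Actb, Gapdh and Tfrc could be read.

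Those names come from the array's control probe sets, whose IDs spell out actin, Gapdh, the transferrin receptor, pyruvate carboxylase, 18S ribosomal RNA and B1 and B2 repeats. They are written here as Actb, Gapdh, Tfrc, Pcx and 18S rRNA, and they target the 3' end, the middle or the 5' end of the transcript. Pcx and 18S rRNA lie outside the rule for named genes and were added after the values were seen, as were the ratios to Actb and the values of the hybridization controls. Of the 2 middle probe sets of Pcx, the one called A in its ID was used for ratios. Values of these transcripts, and their ratios to the Actb probe set of the same part within each array, were compared by two-sided exact permutation tests over the 70 assignments of 8 arrays. The smallest p this design can give is 0.0286. Benjamini-Hochberg adjustment ran over 19 named probe sets, over 12 ratios to Actb and over 4 ratios between parts of a transcript. Intervals at 95% were found by inverting the same exact test. The mean over 18 probe sets for bacterial and phage hybridization controls gave one value per array. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

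Alternatives chosen before the data were examined were a filter on dim probe sets, quantile normalization, centring of each array on its median, a trended and robust prior, array weights, a minimum change of 2-fold, an adjusted p under 0.01, the replicate number as a block, each array left out in turn, the authors' SAM table, and the middle in place of the 5' control probe sets. Alternatives chosen after seeing the data were centring on the hybridization controls or on Actb, offsets of 16 and 100 before log2, the probe sets of the authors' table alone, the block together with the trended prior, other parts of the named transcripts, and the brightest 100 in place of 500 probe sets.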

Results

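The data were whole-blood transcript levels of mice under normobaric hypoxia, a lowering of the oxygen content of the air at normal pressure, and of mice at room condition, with 4 arrays in each group. RNA came from 100 µl of blood in control and 500 µl in hypoxia, so every difference between the groups is also one between these volumes. The comparison asks which transcripts of whole blood differ after 15 days in the chamber. The median intensity per array was 187 ± 18.4 (SD, n = 4) in control and 236 ± 7.24 (SD, n = 4) in hypoxia, after scaling of all arrays to a trimmed mean of 500. Across probe sets, which are not independent replicates, the log2 values of control arrays correlated with each other at a Pearson r of 0.769 to 0.796. Hypoxia arrays correlated with each other at 0.673 to 0.718, and arrays of different groups at 0.631 to 0.707.

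Relative to Actb, which encodes a cytoskeletal actin, the transcripts of Gapdh, Tfrc, Pcx and 18S rRNA were all higher in hypoxic blood when measured at their 3' ends. Gapdh, a glycolytic enzyme, rose 2.28-fold against Actb at the 3' probe sets. Tfrc, the transferrin receptor through which cells take up iron, rose 3.50-fold against Actb at the same end on the deposited scale. Quantile normalization changed the size of that rise. Pcx, the mitochondrial pyruvate carboxylase that makes oxaloacetate, was higher from a control level too dim to give its fold. 18S rRNA, the RNA of the small ribosomal subunit, rose 2.02-fold at its 3' probe set and 4.82-fold at its middle one on the deposited scale, an order that turned under quantile normalization.

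For Gapdh, the log2 ratio to Actb went from -0.99 ± 0.07 (SD, n = 4) in control to 0.20 ± 0.29 (SD, n = 4) in hypoxia, a change of 1.19 with an SE of 0.15. The exact permutation test gave p = 0.0286, the smallest the design allows, and an adjusted p of 0.0343 over 12 ratios. All 4 hypoxia arrays lay above all 4 control arrays. The same held at the middle probe sets, with a change of 1.33 (SE 0.16), and at the 5' probe sets, with a change of 1.25 (SE 0.19). In the authors' deposited table, made from other values, the log2 difference of Gapdh exceeded that of Actb by 1.33 at the 3' end, 1.57 in the middle and 1.23 at the 5' end. These ratios show that the transcripts changed unequally, and they leave open which of them moved.

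Whether Actb alone or Gapdh alone passed the threshold at the 3' end depended on the scaling. As deposited, Gapdh intensity at the 3' end was 26756 ± 3023 (SD, n = 4) in control and 62675 ± 12016 (SD, n = 4) in hypoxia, a 2.32-fold rise (exact permutation p = 0.0286, adjusted p = 0.0418 over 19 probe sets), whereas quantile normalization gave a log2 change of -0.02 (exact p = 0.886) and centring on the hybridization controls gave 0.28 (exact p = 0.314). Under quantile normalization Gapdh was at 0.62 in the middle (exact p = 0.0286) and at 0.37 at the 5' end (exact p = 0.0857). Actb at the 3' end changed by 0.03 (SE 0.17, exact p = 0.943) as deposited, and by -1.27 after quantile normalization and -0.91 after centring on the hybridization controls, both with exact p = 0.0286. As deposited, Actb changed by -0.18 in the middle (exact p = 0.343) and by -0.30 at the 5' end (exact p = 0.0571). The authors' deposited table listed Actb at -1.22 with a q-value of 0% and Gapdh at 0.11 with a q-value of 22.6% at the 3' end, 0.51 with a q-value of 4.26% in the middle and 0.30 with a q-value of 15.2% at the 5' end.

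Tfrc intensity at the 3' end was 340 ± 119 (SD, n = 4) in control and 1254 ± 573 (SD, n = 4) in hypoxia. Its log2 ratio to Actb was higher by 1.81 (SE 0.45), with all 4 hypoxia arrays above all 4 controls (exact permutation p = 0.0286, adjusted p = 0.0343). At the other parts the difference missed the threshold, and whether it differed from that at the 3' end was not tested. It was 1.00 (SE 0.39, exact p = 0.0571, adjusted p = 0.0623) at the middle and 0.46 (SE 1.08, exact p = 0.686) at the 5' probe set, where hypoxia intensities ranged from 25.2 to 309. With 1 array left out that 5' difference changed sign, running from -0.17 without hypoxia 2 to 1.23 without hypoxia 4. The ratio at the 3' end also moved to an exact p of 0.0571 when control 2, control 4, hypoxia 1 or hypoxia 3 was left out. Under quantile normalization the ratio was higher by 3.14 at the 3' end and 1.78 in the middle, both with exact p = 0.0286, and by 0.92 at the 5' end (exact p = 0.429). Taken alone, Tfrc at the 3' end was 3.57-fold higher as deposited (exact p = 0.0286), and after centring on the hybridization controls it was higher by 0.90 log2 units (exact p = 0.143). In the authors' deposited table Tfrc was higher by 1.33 at the 3' end with a q-value of 0.0655%, and by 0.25 in the middle with a q-value of 19.3%, which is 2.55 and 1.31 more than Actb.

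Pcx stood at 54.8 ± 39.1 (SD, n = 4) in control and 361 ± 33.5 (SD, n = 4) in hypoxia at the 3' end. Against Actb it was higher at the 3' end, in the middle and at the 5' end, each with separated groups and exact p = 0.0286. The exact p moved to 0.0571 in the middle when any control array was left out, and to 0.0857 at the 5' end when any hypoxia array was. In the authors' deposited table the middle probe set A was higher by 0.52 with a q-value of 2.62%, which is 1.58 more than Actb. A further middle probe set, called B in its ID, differed by 0.57 before any ratio was taken (SE 1.27, exact p = 0.714). The control intensities of Pcx at the 3' end, 17.8 to 92.9, lay below the median intensity of every control array, and those of probe set A, 16.1 to 26.9, lay in the range of the dimmest 10% of probe sets, which ended at 33.4. 18S rRNA at the middle probe set had an intensity of 20118 ± 2882 (SD, n = 4) in control and 85470 ± 11874 (SD, n = 4) in hypoxia. Its ratio to Actb rose by 2.27 (SE 0.12) at the middle, 1.01 (SE 0.30) at the 3' and 1.85 (SE 0.30) at the 5' probe set, all with exact p = 0.0286. That p moved to 0.0571 at the 3' probe set without any 1 hypoxia array and at the 5' probe set without control 1, 2 or 4. Under quantile normalization the rises were 1.93 at the middle, 2.50 at the 3' and 2.62 at the 5' probe set, all with exact p = 0.0286. Taken alone and centred on the hybridization controls, 18S rRNA was higher by 1.15 at the middle (exact p = 0.0286). It was then higher by 0.10 at the 3' (exact p = 0.486) and by 0.61 at the 5' probe set (exact p = 0.0571). In the authors' deposited table its difference exceeded that of Actb by 1.93, 2.30 and 1.99 at these parts. Ribosomal RNA has no poly(A) tail, and the labelling started from oligo(dT), so this signal measures what the primer copied.

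**Figure D1:**
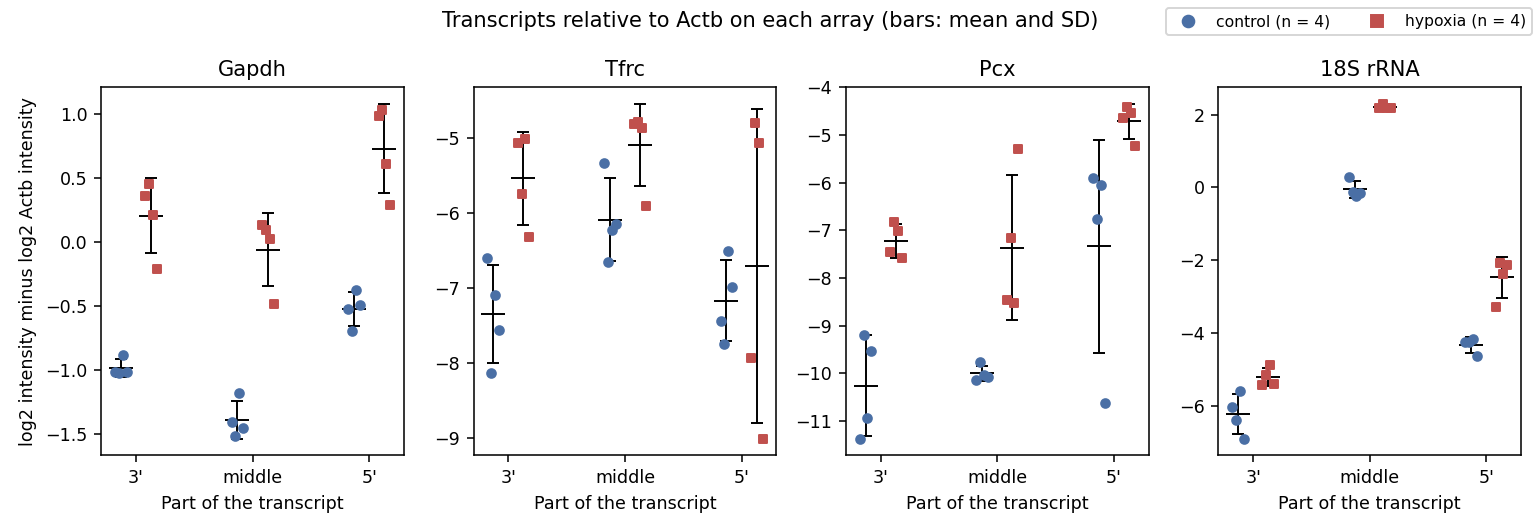
Log2 intensity of Gapdh, Tfrc, Pcx and 18S rRNA minus that of Actb on each array (vertical axis) at the 3', middle and 5' probe sets (horizontal axis); blue circles are the 4 control arrays, red squares the 4 hypoxia arrays, and bars give mean and SD. The groups are apart at all parts of Gapdh, Pcx (middle probe set A) and 18S rRNA, and for Tfrc at the 3' end, where the change was 1.81; a ratio shows unequal change and not which transcript moved.

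As deposited, the share of transcript ends differed between the groups as well. The 3' over 5' intensity ratio of Actb was 4.05 in control (log2 2.02 ± 0.16, SD, n = 4) and 5.09 in hypoxia (log2 2.35 ± 0.08, SD, n = 4). The difference of 0.33 (SE 0.09) had an exact permutation p of 0.0286 and an adjusted p of 0.0381 over 4 ratios. For Gapdh the ratio was 2.94 in control and 3.54 in hypoxia, a difference of 0.27 (SE 0.08, exact p = 0.0286). The 3' over middle ratio rose for Actb by 0.21 (SE 0.06, exact p = 0.0286) and differed for Gapdh by 0.07 (SE 0.04, exact p = 0.171). With any 1 hypoxia array left out the 3' over 5' differences were 0.30 to 0.36 for Actb and 0.23 to 0.29 for Gapdh, with exact p = 0.0571 in these smaller sets. The authors' deposited table gave the opposite sign, with log2 differences, 3' minus 5', of -0.28 for Actb and -0.18 for Gapdh. Quantile normalization of the deposited intensities turned the sign as well. Under it Actb changed by -1.27 at the 3' end and -0.93 at the 5' end, and Gapdh by -0.02 and 0.37. The direction of this end bias thus depended on the processing.

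**Figure D2:**
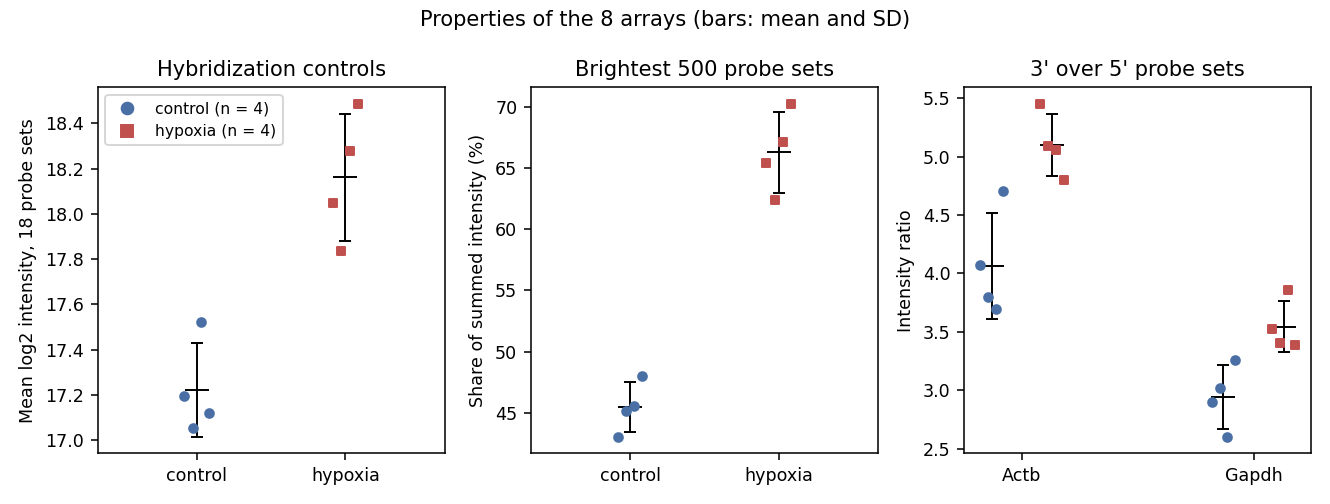
Mean log2 intensity of 18 hybridization control probe sets (left), share of the summed intensity in the brightest 500 probe sets in percent (middle) and 3' over 5' intensity ratio of Actb and Gapdh (right) for the 4 control (blue circles) and 4 hypoxia arrays (red squares), with mean and SD. The share was 43.0% to 48.0% on control arrays and 62.4% to 70.3% on hypoxia arrays, and the Actb ratio 3.70 to 4.70 against 4.80 to 5.45.

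On the hypoxia arrays a larger part of the signal lay in few probe sets. The brightest 500 probe sets held 45.4% ± 2.04 (SD, n = 4) of the summed intensity on control arrays and 66.3% ± 3.30 (SD, n = 4) on hypoxia arrays, a gain of 20.9 percentage points (SE 1.94, exact permutation p = 0.0286). The brightest 100 held 20.1% ± 0.675 (SD, n = 4) and 30.7% ± 2.20 (SD, n = 4). The hybridization controls, bacterial and phage RNA added to the sample, were 1.92-fold brighter on the hypoxia arrays (log2 difference 0.94, SE 0.17, exact p = 0.0286).

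Across the whole array, 1643 probe sets were higher and 1173 lower in hypoxia by limma at an adjusted p under 0.05, together 6.25% of the 45037 tested. The files do not pair these IDs with genes. The largest rises were those of probe set 1417311_at, by 6.52 log2 units (SE 0.97, adjusted p = 0.0145), and of 1425927_a_at, by 6.51 (SE 0.51, adjusted p = 0.00869). For 1425927_a_at the log2 intensity went from 7.43 ± 0.65 (SD, n = 4) to 13.93 ± 0.70 (SD, n = 4). The level of 1417311_at went from 4.45 ± 2.08 (SD, n = 4) to 10.97 ± 0.69 (SD, n = 4), and its control intensities, between 6.04 and 141, make the size of that rise uncertain. The order of these rises turned with array weights, without control 1, control 4 or hypoxia 4, with an offset of 16 before log2, where 1417311_at changed by 5.50 and 1425927_a_at by 6.37, with an offset of 100, where they changed by 3.94 and 5.83, and in the authors' deposited table. The largest falls on the deposited scale were those of 1455905_at, which decreased by 4.90 (SE 0.62, adjusted p = 0.0121), and 1419769_at, which decreased by 4.87 (SE 0.60, adjusted p = 0.0119). Their hypoxia levels were 4.73 ± 1.19 and 4.28 ± 1.06 on the log2 scale (SD, n = 4), in the dim range, and with an offset of 100 the changes were -2.75 for 1455905_at and -2.45 for 1419769_at. In the authors' deposited table the differences of these 4 probe sets were smaller in size, at 3.77 for 1417311_at, 5.45 for 1425927_a_at, -1.89 for 1455905_at and -2.33 for 1419769_at, each with a q-value of 0%. The largest fall in the authors' deposited table was another one, with a signed fold of -15.5.

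Every called change was at least 2-fold, and 1192 rises and 632 falls were at least 4-fold. At least 16-fold were 102 rises and 25 falls. The median size of a called change was 2.24 log2 units. In 9435 probe sets, or 20.9%, all 4 hypoxia values lay on one side of all 4 control values, against 2.86% by chance. Of these, 4719 were higher and 4716 lower as deposited. The array medians were separated between the groups on that scale too, and these counts were not repeated under other scalings.

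The balance of rises and falls depended on the scaling and on other settings. Rises made up 58.3% of calls on the deposited scale, 31.1% after centring each array on its median, 8.82% after centring on the hybridization controls and 72.5% after centring on Actb. On the deposited scale they made up 45.7% with a trended and robust prior, 47.1% with the filter on dim probe sets, 44.5% among the authors' probe sets alone, and 52.2% to 86.2% with 1 array left out. They made up 33.4% of the probe sets with a q-value under 5% in the authors' deposited table, where 4101 were higher and 8186 lower. The median change of all probe sets was 0.19 log2 units as deposited, 0.00 after quantile normalization, -0.15 after median centring and -0.74 after centring on the hybridization controls. Relative to the array median, the 3' probe sets changed by 0.88 for Gapdh, 1.49 for Tfrc and by 1.75 for 18S rRNA at its middle probe set, each with exact permutation p = 0.0286. The counts themselves rested on all 8 arrays: without 1 array they fell to between 384 and 1367 rises and moved to between 76 and 1250 falls, and leaving out any array other than hypoxia 2 lowered both counts by over 1.5 times.

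The calls lay mainly among bright probe sets. In the brightest 10% of probe sets, with a mean intensity of 1177 or more, 851 were higher and 528 lower, or 30.6%. In the dimmest 10%, 99 were higher and 21 lower, or 2.66%. The median SD of the control arrays was 1.63 log2 units in the dimmest 10% and 0.29 in the brightest 10%. Changes were thus easier to detect among bright probe sets. The median change fell with brightness from 0.79 log2 units in the dimmest 10% to -0.17 in the brightest 10%, with a minimum of -0.36 in the class just below the brightest. The authors' deposited table gave medians of 0.53 for its probe sets in the dimmest class, -0.46 in the brightest and -0.55 in the class just below. It listed only 101 of the 4504 probe sets in the dimmest class, against 4503 of 4504 in the brightest, so its median for the dimmest class covers a small part of that class.

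**Figure D3:**
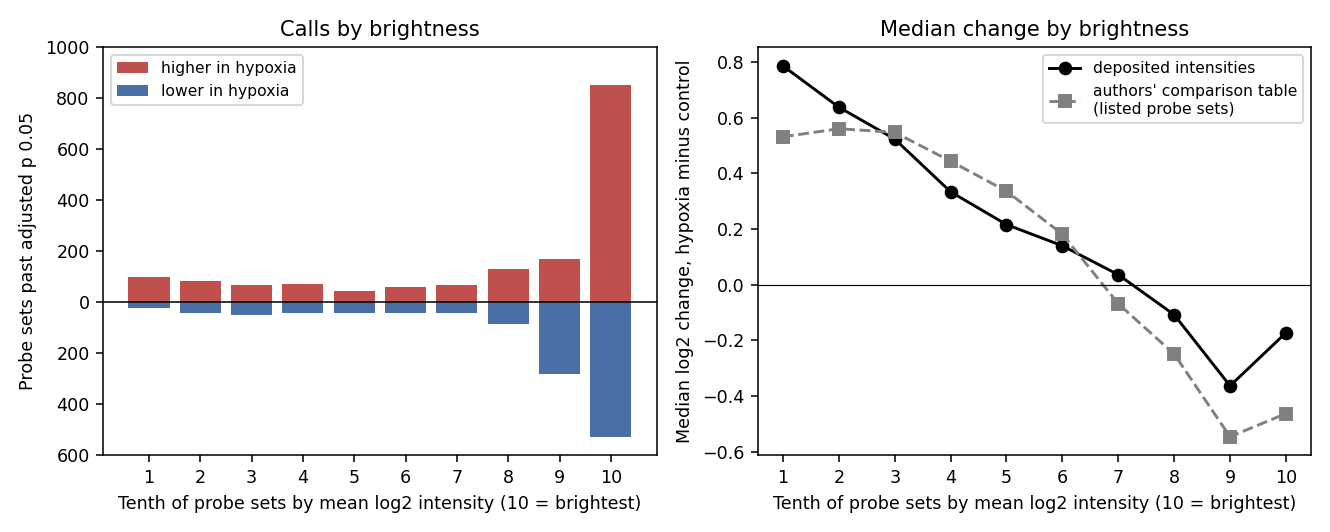
Probe sets higher (red, above 0) and lower (blue, below 0) in hypoxia at an adjusted p under 0.05 (left) and median log2 change, hypoxia minus control (right), in 10 equal classes of probe sets ordered by mean log2 intensity over all 8 arrays. The brightest class holds 851 rises and 528 falls, and the median goes from 0.79 in the dimmest to -0.17 in the brightest class on deposited intensities (circles) and from 0.53 to -0.46 in the authors' deposited table (squares). The squares cover listed probe sets only, 101 of 4504 in the dimmest class and 4503 of 4504 in the brightest.

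Across the 19916 probe sets listed in the authors' deposited table, the log2 differences there and those fitted here had a Pearson r of 0.870 and a Spearman rho of 0.891. These are correlations across probe sets, which are not independent replicates, of the same 8 arrays. The listed probe sets were brighter than the rest, with a median level of 8.95 against 6.28 on the log2 scale. Of the 2816 calls made here, 2325 were listed, and 2233 of these had a q-value under 5% with the same sign. Among all 19916 listed probe sets, 12287 had a q-value under 5%, so much of this overlap in calls follows from that share.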

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

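All tests in this part were chosen after the results were seen, except the count over other splits of the arrays and the ratio of SDs with each hypoxia array left out. The hybridization controls lay outside the comparison of transcripts and were higher in hypoxia by 0.94 log2 units (95% interval 0.32 to 1.43 by the exact test). Among 102 groups of 4 arrays examined, 7 held an array far from the other 3, where chance gives about 5.1 at Dixon's 95% limit.

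The arrays concerned were these. Control 3 had a mean Pearson r with the hypoxia arrays of 0.654, against 0.660 to 0.661 for the other controls. Gapdh at the 5' end stood at 14.47 on the log2 scale in hypoxia 1, against 13.95 to 14.00 in the others. Pcx at the 5' end stood at 3.06 in control 4, against 7.05 to 7.64. For 18S rRNA at the middle probe set, control 3 had 13.95, against 14.36 to 14.43. The log2 ratio of Gapdh to Actb at the 3' end was -0.89 in control 3, against -1.03 to -1.01. The ratio of Tfrc to Actb in the middle was -5.92 in hypoxia 4, against -4.87 to -4.79. For 18S rRNA over Actb in the middle, hypoxia 2 had 2.30, against 2.19 in each of the other 3.

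The number of calls was set against other groupings of the same arrays. Of the 35 splits of 8 arrays into 4 and 4, only 1, the real one, gave as many as 2816 calls, and the highest count among the others was 0. A share of 1 in 35 lies under 0.05, so chance can be excluded at that level, and 35 splits allow no smaller share. The other splits mix the groups, which widens their residual spread and lowers their counts.

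Hybridization controls were 0.94 log2 units brighter on hypoxia arrays, and the dimmest 10% of probe sets was higher by 0.78. If more control RNA had been added there, the summed signal per unit of control would have fallen by about as much. It changed by -0.11 (SE 0.13, exact permutation p = 0.400), and the lower end of its 95% interval, -0.43, argues narrowly against such an excess as the whole source. A candidate explanation is that the signal of hypoxic blood is concentrated in bright probe sets, which a trimmed scaling leaves out, so that all else is scaled up, and the value of -0.11 is in line with it. The dimmest 10% changed by -0.15 relative to the controls (SE 0.12, 95% interval -0.60 to 0.19), in line with a background lifted by the same factor, though the interval is wide.

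Gapdh was higher relative to Actb in hypoxia by 1.19 log2 units at the 3' end. At the 5' probe sets the rise was 1.25 with separated groups. A bias that lowered the 5' signal of Actb more than that of Gapdh would also raise the 5' ratio. The 5' rise alone thus cannot decide on a stronger 3' bias of the hypoxia RNA as the cause. However, the log2 3' over 5' ratio rose nearly alike, by 0.33 (SE 0.09) for Actb and 0.27 (SE 0.08) for Gapdh. In the authors' deposited table it changed the other way, by -0.28 and -0.18. These values argue against such a bias as the whole cause. A scaling of the deposited values by 1 factor per array cannot be the cause, since it cancels in a ratio within an array. In the authors' deposited table, made from other values, the difference was 1.33, so it was not particular to the deposited intensities. The blood volume used for RNA isolation stays open: 0 groups hold arrays of both volumes, so an effect of volume and an effect of hypoxia cannot be told apart. Hypoxia itself, through levels per cell or through the mix of blood cells, stays open too and was not tested.

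In the brightest 10% of probe sets the median SD of the hypoxia arrays was 1.37 times that of the controls, though the distance of an array from the rest of its group missed the threshold there (exact permutation p = 0.0857). The larger spread was not confined to probe sets that are dim on the scaled intensities. In the 4 classes of 10% below the brightest, that distance was 1.37 to 1.56 times as large in hypoxia with separated groups (each exact p = 0.0286, adjusted p = 0.0408). It was 0.954 and 1.00 times as large in the 2 dimmest classes. These classes were not matched for signal over background, so they cannot decide on noise of weak signal as the cause. A single deviant hypoxia array is argued against by the ratio of SDs, which was lowest without hypoxia 2 and still 1.16 there, and by those 4 classes, where every pair of hypoxia arrays lay further apart than any pair of controls. A candidate explanation is a weaker signal over background at the same scaled intensity: with hypoxia levels lowered by the rise of the hybridization controls, the ratio of distances at matched level had a median of 1.06 over the 5 classes above the median, against 1.37 with the same classes and no shift. It was still 1.17 and 1.28 in the 2 brightest classes (exact p = 0.0857 and 0.257), so a wider range of responses to hypoxia stays open there and was not tested.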

How the results depend on the processing

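Chosen after seeing the data were the offsets, centring on hybridization controls or Actb, the authors' probe sets alone, the block with a trended prior, all scalings and other parts of the named transcripts, and all results for Pcx, 18S rRNA and ratios to Actb. Against 1643 higher and 1173 lower probe sets, the filter on dim probe sets gave 3006 and 3382, the trended and robust prior 3123 and 3713, an offset of 100 gave 3476 and 3639, the authors' probe sets alone 2852 and 3558, and the authors' SAM table gave 4101 and 8186. Hybridization control centring gave 593 and 6129, Actb centring 1074 and 408, median centring 2433 lower and an offset of 16 1908 lower. An adjusted p under 0.01 left 5 and 0 by limma, with 11517 at an unadjusted p under 0.05. Quantile normalization, array weights and the 2-fold minimum, which removed nothing, kept both counts within 1.5 times. The filter and the restriction to listed probe sets test fewer and brighter probe sets; for the rest the cause was not tested.

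Without 1 array, counts ran from 384 to 1367 higher and 76 to 1250 lower: 438 and 76 without control 1, 474 and 76 without control 2, 384 and 78 without control 3, 858 and 219 without control 4, 686 and 295 without hypoxia 1, 550 and 262 without hypoxia 3, and 900 and 593 without hypoxia 4. Fewer arrays widen the error; without hypoxia 2 there were 1367 and 1250. The changes of the 4 probe sets named by ID passed the threshold in each of these 8 runs; with an offset of 100, 1417311_at changed by 3.94, 1455905_at by -2.75 and 1419769_at by -2.45, since an offset shrinks dim values. Tfrc relative to Actb ranged from 1.55 to 2.07, the 3' over 5' ratio of Actb from 0.29 to 0.40 and of Gapdh from 0.21 to 0.32, each with exact permutation p from 0.0286 to 0.0571. The change of Actb ranged from -0.047 to 0.16. Relative to Actb, Gapdh and Pcx at the 3' end and 18S rRNA at the middle kept their direction and p = 0.0286 in all 8 exact tests.

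Tfrc relative to Actb was 1.00 at the middle and 0.46 at the 5' probe sets, and within Gapdh the change of the 3' over middle ratio was 0.068. Actb alone became -1.27 under quantile normalization, -0.31 under median centring and -0.91 under hybridization control centring, and Gapdh -0.015 under quantile normalization; the cause was not tested.

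The replicate number as a block gave 0 and 0 calls by limma, with 10348 at an unadjusted p under 0.05, and 2886 and 3594 with a trended and robust prior. Arrays of equal number did not deviate together: their correlations, across probe sets, were 0.034, -0.037, -0.026 and -0.052, so the numbers only name the samples. Not run for want of gene names were the mean of probe sets or 1 probe set per gene, centring on leukocyte or reference genes, and all alternatives of gene lists and leukocyte classes. Dim probe sets, at an SD of about 1.6 log2 units in the dimmest 10%, limit what 4 arrays per group can show.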

Other observations

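The tests in this part were chosen after the values were seen. The B1 and B2 repeats, short interspersed elements found in many mouse transcripts, were brighter on hypoxia arrays as deposited, by 0.70 log2 units for B1 and by 0.81 and 1.01 for 2 B2 probe sets (each exact permutation p = 0.0286, adjusted p = 0.0418 over 19 probe sets, 4 of 4 hypoxia arrays above all controls). B1 was at -0.24 under hybridization control centring (exact p = 0.171) and at -0.53 under quantile normalization (exact p = 0.143), so neither differed from no change. The first B2 probe set was at -0.13 under hybridization control centring (exact p = 0.343), and the second turned to -0.37 under quantile normalization (exact p = 0.0286). The first stayed higher under quantile normalization, by 0.65 (exact p = 0.0286), and the second was at 0.08 under hybridization control centring (exact p = 0.314). Under median centring all 3 probe sets stayed higher, by 0.36, 0.47 and 0.67 (each exact p = 0.0286). In the authors' deposited table B1 was listed at -0.44 with a q-value of 2.62%, the first B2 probe set at 0.05 with a q-value of 23.7% and the second at -0.35 with a q-value of 1.91%.

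Hypoxia 2 stood nearest to the control arrays. Its mean Pearson r with controls across probe sets was 0.702, against 0.638 to 0.651 for the other hypoxia arrays, a gap that stayed within Dixon's limit. The slope of its deviations from control on the mean of the other 3 hypoxia arrays, over the brightest 10% of probe sets, was 0.73, against 1.00 to 1.11.

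The 18 hybridization control probe sets, brighter on all 4 hypoxia arrays as deposited, had log2 differences between -0.43 and -0.02 in the authors' deposited table. There 8186 probe sets were lower and 4101 higher at a q-value under 5%, and among the brightest 10% of probe sets 2320 were lower and 1130 higher.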
